A study of Mus musculus with 24 samples.

How the data were processed

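RNA from mouse (BALB/c) splenic B cells was measured in 24 libraries in 8 groups of 3: early, peak and late germinal center (GC) B cells, in vivo activated B cells, naive B cells, and B cells 4 h, 12 h and 24 h after in vitro activation. Per the labels' protocols, cells were bead purified, stained with antibodies and sorted, RNA was isolated with the RNeasy Plus Micro Kit, libraries were made with the TruSeq Stranded mRNA kit, and paired reads of 75 bases were sequenced on a NextSeq 500. The labels name no stimulus, immunogen, day, animal, culture or sex.

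Per the submitters' processing notes, FastQC 0.11.5, cutadapt 1.8.3, STAR 2.6.0c, featureCounts, Subread 1.6.2 and limma were used with the mm10 genome; the counting options and the limma steps are not described there. The deposited values of each library are log2 values on a scale like CPM, as read from the values themselves: the sums of 2 to the power of the deposited log2 values lay between 990678 and 1008194. The values show further steps that no label records. All libraries share nearly one distribution, since the value at rank 1000 from the top differed by at most 0.03 log2 between libraries. For each gene, the mean over the libraries of one replicate number equals that over each other number, with a largest difference of 0.0009 log2. The median of that difference was 0.00013 log2, against 0.063 to 0.085 log2 in 20 shuffles of the numbers within groups. A difference between replicate numbers, if there was one, had therefore been taken out of the deposited values. The most frequent value was -6.178 log2. Values under -5 log2 are called the floor here, and 5895 of 23420 genes were there in all libraries. The depth per library is unknown, so no limit of detection could be computed. No immunoglobulin or T-cell receptor gene segment is among the symbols (0 found).

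The design written before the data were examined assumed counts and a count-based test. Because the files hold normalized log2 values, limma 3.58.1 in R 4.3.3 was used in its place on the values as deposited, with one mean per group over all 24 libraries, a variance trend, robust moderation and 16 residual degrees of freedom. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes with at least 1 CPM (a log2 value of 0) in at least 3 libraries were tested, which left 11885 genes. Every adjusted p is from limma, two-sided, with Benjamini-Hochberg adjustment over the genes tested in that comparison, and a gene is called changed at an adjusted p under 0.05. Fold changes are log2 with their standard errors (SE); group values are log2 means with the standard deviation (SD) over 3 libraries. Gene symbols were matched to an mm10 annotation, 21571 directly and 1689 by a synonym, with 160 unmatched. Reads of near-identical gene copies could be split by the counting, so single members of gene families such as H2-DMb1 and H2-DMb2 or Bcl2a1b and Bcl2a1d are uncertain.

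The 13 comparisons, 34 gene lists and 10 lists of cell type markers were chosen before the data were examined. The gene lists were GC B-cell, naive follicular B-cell, light zone, dark zone, memory B-cell and plasma cell genes; subunits of complex I, of complexes III and IV and of ATP synthase; the TCA cycle, glycolysis, mitochondrial fatty acid oxidation, peroxisome, lipid uptake and lipolysis, fatty acid synthesis, cholesterol synthesis, the pentose phosphate pathway, and serine and one-carbon metabolism; ribosome biogenesis, S phase, mitosis, and mutation and repair genes; immediate-early, NF-kB target, interferon response, unfolded protein response, hypoxia and MHC class II presentation genes; pro-apoptotic and anti-apoptotic genes; and B-cell receptor signalling, heat shock, amino acid transport, and autophagy and lysosome genes. The marker lists were T cells, macrophages and monocytes, neutrophils, dendritic cells, NK cells, erythroid cells, platelets, stroma, plasma cells and marginal zone B cells. A list was tested where at least 3 members were, with camera from limma at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. Camera compares a list with all other tested genes. It was rerun with a correlation estimated from the data for each list, and fry was run beside it, which tests the net direction of a list and compares it with no other genes.

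Genes are named by a rule also fixed at that stage. Its first part takes, per comparison, up to 8 genes in each direction with the largest fold changes among those changed at least 2-fold, with a mean of at least 10 CPM in the higher group, no overlap between the groups' libraries, and no unnamed gene model. Its second part takes up to 4 members of each list by the smallest p, up to 2 in each direction where both passed. The third part is a fixed set of genes for the label check. Some genes that these rules select are not reported here. For a gene with a group mean under -5 log2, no fold is printed and it is said to be at the floor. Genes set apart in one kind of cell were chosen after the values were seen.

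The fit and camera were run on simulated data for 11885 genes, 200 changed by known folds. Over 13 comparisons, 61.2 to 79.1% of 1.5-fold, 73.1 to 94% of 2-fold and 84.8 to 100% of 4-fold changes were recovered. The shifted list was called in 13 of 13 comparisons but 0 others were by camera. Of 100 calls, 6.5 to 12.9 were unchanged genes, above the 5 aimed at. The simulation removed replicate-number differences as in the data, while the fit counted those degrees of freedom. With the replicate number as a block (14 residual degrees of freedom) 3 to 7.9 were unchanged. Real list members correlate and up to 84.8% of genes changed, so these rates may not carry over. Alternatives tried were no filter and a filter at 5 CPM, only the libraries of both groups, the replicate block, each library left out in turn, shifts of each library by the trimmed mean or the median of log ratios, no variance trend and no robust fit, log2 of CPM plus 1, an estimated correlation and fry. A covariate made of macrophage, neutrophil and erythroid markers was added after the values were seen.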

Results

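Expression of 23420 genes was measured in 24 libraries of splenic B cells from BALB/c mice, 3 libraries in each of 8 groups: naive, 4 h, 12 h and 24 h in vitro activated, in vivo activated, and early, peak and late germinal center (GC) cells. The labels ask how freshly isolated GC B cells differ in their RNA from naive and activated B cells, and how the 3 GC stages differ. Values are deposited log2 values on a scale like CPM. As the labels name no animals or cultures, the p-values measure only the spread between these libraries, pooled over all groups. Fold changes are log2 with SE, group values are log2 means with SD (n = 3), and adjusted p is from limma. Member counts of a gene list are over all genes tested, and the count adjusted over the list alone is given where it differs or for the lists described first. Every gene named among the largest changes had all 3 libraries of one group above all 3 of the other.

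The first principal component held 55.2% of the variance, the second 20% and the third 11.1%. Replicates correlated across genes at 0.986 to 0.998, although genes are not independent replicates.

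**Figure D1:**
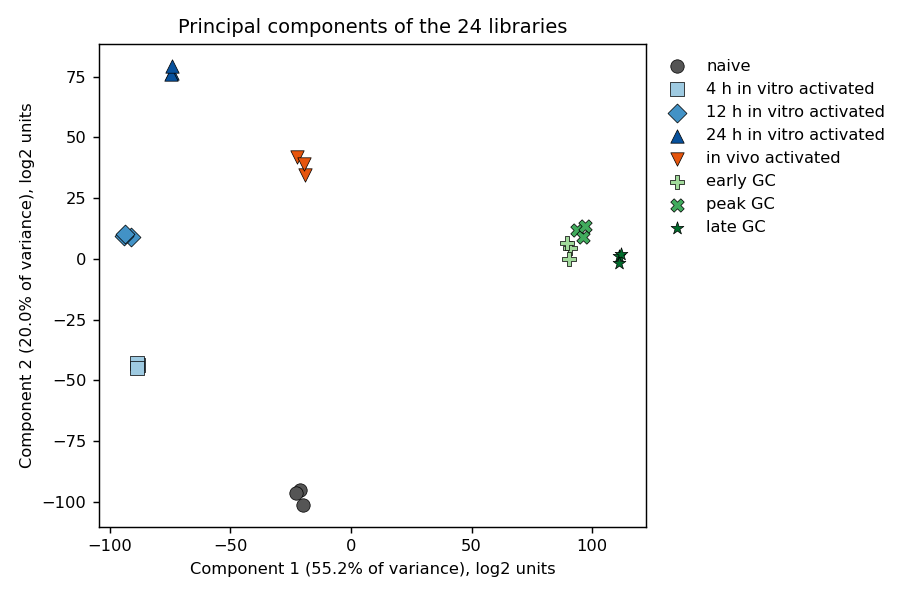
The 24 libraries on the first and second principal components of the tested genes. Each point is a library, and colour and shape give the group.

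Genes that mark GC B cells in general were high in the GC groups. S1pr2, a receptor that keeps B cells in the GC (mm10 9:20965952-20976793), had log2 values of 8.63 ± 0.16 (SD, n = 3), 8.73 ± 0.03 and 8.56 ± 0.07 in early, peak and late GC cells, 3.18 ± 0.03 in naive and 1.31 ± 0.04 in in vivo activated cells. Bcl6, the repressor needed for the GC (16:23965050-23988866), had 7.8 ± 0.14 in peak GC and 6.72 ± 0.04 in naive cells. It was low in in vivo activated cells (2.71 ± 0.31) and had 5.72 ± 0.36, 4.34 ± 0.02 and 2.77 ± 0.2 at 4 h, 12 h and 24 h in vitro. Fas had 6.01 ± 0.22 in peak GC and 2.63 ± 0.12 in naive cells. Cd38, a surface enzyme of naive mouse B cells (5:43868809-43912374), had 3.77 ± 0.12, 2.16 ± 0.32 and 0.25 ± 0.18 in early, peak and late GC cells, 6.97 ± 0.03 in naive and 7.69 ± 0.12 in in vivo activated cells. Mki67, made by dividing cells (7:135689784-135716450), had 10.05 ± 0.26 in peak GC, 9.33 ± 0.11 in in vivo activated and 5.08 ± 0.15 in naive cells, and 2.48 ± 0.04, 2.78 ± 0.11 and 8.39 ± 0.07 at 4 h, 12 h and 24 h.

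Genes that are quickly induced on activation were already high in naive cells: Cd69 had 9.21 ± 0.23 and Myc 9.25 ± 0.13 there, against 6.79 ± 0.23 and 6.62 ± 0.3 in peak GC and 8.8 ± 0.07 and 9.33 ± 0.04 at 4 h in vitro. Cd86 had 6.19 ± 0.04 in naive cells and 8.86 ± 0.1 at 4 h. Ccr7 and Fcer2a (CD23) had 10.33 ± 0.32 and 10.59 ± 0.14 in naive cells, and Irf4 had 10.21 ± 0.11. The Y-linked genes Ddx3y (Y:1260715-1286628), Eif2s3y and Kdm5d had 5.75 ± 0.03, 5.38 ± 0.13 and 4.35 ± 0.05 in naive cells and were at the floor in all 12 GC and in vivo activated libraries. Xist, a noncoding RNA of the inactive X chromosome (X:103460373-103483233), had 6.28 to 7.49 in the naive and in vitro libraries and 7.91 to 8.54 in the others. These Y-linked genes therefore follow the same split as the comparisons of cells from GC or in vivo activation with naive or in vitro cells.

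**Figure D2:**
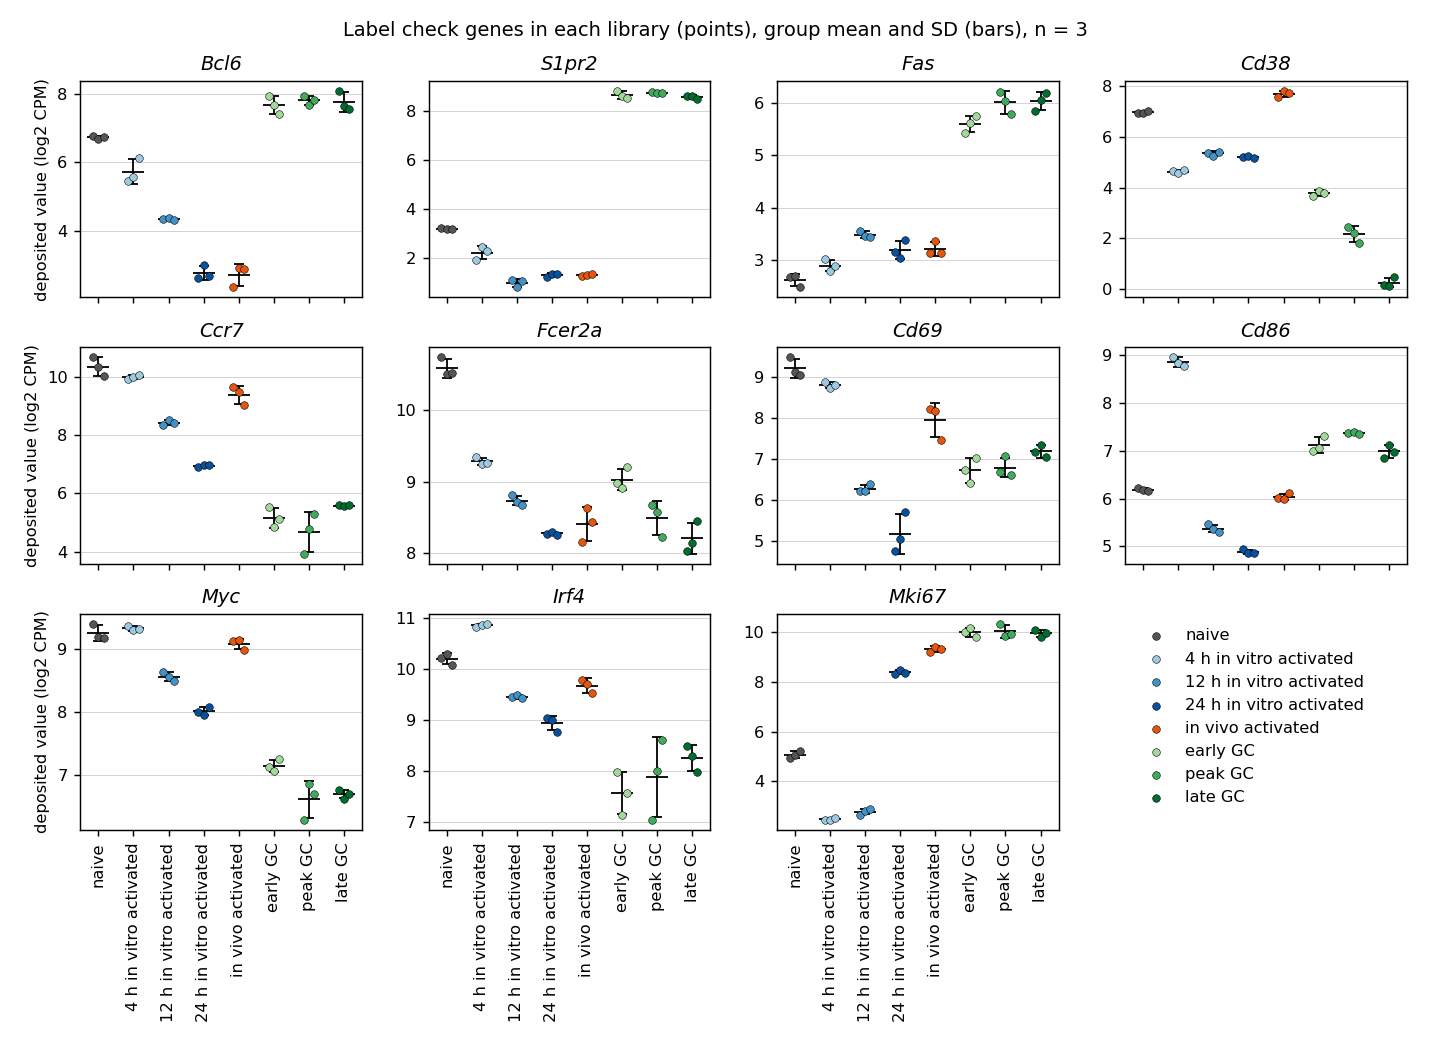
Deposited log2 values of 11 genes used to check the labels. Points are libraries, and bars are the group mean and SD (n = 3).

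From naive to peak GC cells, GC B-cell and DNA synthesis genes rose and naive follicular genes fell. Gcsam, a GC-specific adaptor protein gene (16:45610440-45622867), rose from 1.1 ± 0.28 to 7.81 ± 0.22, a fold change of 6.70 ± 0.28 (adjusted p = 6.91e-16). The linker histone gene H1fx rose by 6.93 ± 0.29, the DNA glycosylase gene Neil3 by 6.50 ± 0.23, the dehydrogenase gene Adhfe1 by 6.52 ± 0.26 and the helicase gene Pif1 by 6.41 ± 0.42, the last with adjusted p = 3.41e-12. Of the GC B-cell genes, 15 of 16 rose and 1 fell (16 changed adjusted over the list alone), with a median of 4.65 (camera adjusted p = 2.85e-07, and adjusted p = 0.00728 with an estimated correlation). Basp1 rose by 5.78 ± 0.11, S1pr2 by 5.56 ± 0.10 and Plxnb2 by 3.66 ± 0.07, while Lmo2 fell by 2.64 ± 0.09. All 15 naive follicular genes fell (15 adjusted over the list alone, median -3.96, adjusted p = 1.39e-08, and 0.0127 with an estimated correlation). Among them the chemokine receptor gene Ccr6 fell by 6.30 ± 0.14, the survival gene Bcl2 by 5.74 ± 0.11, Cd55 by 5.08 ± 0.10 and Cd38 by 4.81 ± 0.11. The surface protein gene Ly6d fell from 8.28 ± 0.24 to 0.14 ± 0.36. Ddx3y, Eif2s3y and Kdm5d went from their naive values to the floor. The marginal zone markers, which are B-cell genes, also fell (9 of 10, median -2.42, adjusted p = 0.00225, and 0.0141 with an estimated correlation). No other marker list was called, with erythroid markers higher in 3 of 4 (median 1.27, adjusted p = 0.998), neutrophil in 3 of 8 (-0.41, 0.998) and stroma lower in 3 of 3 (-1.74, 0.346).

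All 29 mitosis genes rose (29 adjusted over the list alone, median 5.28, adjusted p = 1.23e-16), among them Bub1b by 5.48 ± 0.09 and Ccna2 by 5.29 ± 0.10. The call was lost at adjusted p = 0.136 with an estimated correlation. Of 30 S phase genes 29 rose (median 3.18, adjusted p = 0.0392 with an estimated correlation), such as Uhrf1 by 4.45 ± 0.05 and Mcm6 by 4.11 ± 0.05. Mutation and repair genes rose in 21 of 23 cases (median 1.12, adjusted p = 0.00728 with an estimated correlation), with Lig1 up by 3.65 ± 0.05 and Brca1 by 2.81 ± 0.06, and Atm down by 0.92 ± 0.11. All 22 cholesterol synthesis genes rose (22 adjusted over the list alone, median 1.57, adjusted p = 1.02e-08, and 0.0138 with an estimated correlation), including Sqle by 2.72 ± 0.07 and Cyp51 by 2.57 ± 0.07. Dark zone genes rose in 9 of 12 cases (median 4.11, adjusted p = 0.00245, and adjusted p = 0.211 with an estimated correlation), although Foxp1 fell by 1.78 ± 0.07.

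Of complex I genes 31 of 35 rose (median 0.57), of complexes III and IV 21 of 21 (median 0.7, Cox6c by 0.99 ± 0.05), of ATP synthase 14 of 15 (median 0.78, Atp5a1 by 1.26 ± 0.04) and of the TCA cycle 15 of 19 (median 0.44, Sdhd by 1.25 ± 0.06). Camera called all 4 lists, with adjusted p of at most 4.80e-04, but adjusted p = 0.383, 0.28, 0.215 and 0.257 with an estimated correlation. Serine and one-carbon genes rose in 12 of 14 cases (median 1.1, Psat1 by 3.23 ± 0.07), ribosome biogenesis in 19 of 30 (median 0.37, Npm1 by 1.10 ± 0.06) and amino acid transport in 8 of 11 (median 0.72, Slc7a5 by 1.47 ± 0.10). These calls had adjusted p = 0.215, 0.505 and 0.257 with an estimated correlation. Glycolysis (median 0.59, adjusted p = 0.0744) was not called, although Gapdh rose by 1.77 ± 0.04 and the glucose transporter gene Slc2a3 fell by 2.19 ± 0.06. Fatty acid oxidation was not called either: 9 of 21 genes rose and 8 fell, and its median (-0.01) and mean (0.08) differ in sign.

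In peak GC cells, immediate-early genes fell in 17 of 20 cases (median -2.16, Nr4a1 by 4.09 ± 0.15, Junb by 2.26 ± 0.12), interferon response genes in 20 of 25 (median -1.47, Ddx58 fell by 4.45 ± 0.12), NF-kB targets in 16 of 24 (median -0.82, Nfkb2 by 1.71 ± 0.06) and hypoxia genes in 14 of 19 (median -0.85, Pdk1 by 1.49 ± 0.10). Their calls were lost at adjusted p = 0.257, 0.215, 0.215 and 0.211 with an estimated correlation. MHC class II genes fell in 10 of 12 cases (median -0.51, Ctss by 1.97 ± 0.04), B-cell receptor signalling genes in 18 of 25 (median -0.35, Malt1 by 1.67 ± 0.08, while Cd79b rose by 0.89 ± 0.06) and memory genes in 8 of 12 (median -3.08, while Nt5e rose by 6.25 ± 0.22). These had adjusted p = 0.31, 0.534 and 0.215 with an estimated correlation. Not called were light zone (median -0.44, Cd86 rose by 1.18 ± 0.07, Myc fell by 2.63 ± 0.10), plasma cell (0.72, with a mean of -0.18, Eaf2 rose by 5.12 ± 0.10), lipid uptake and lipolysis (-0.52, Cd36 fell by 3.29 ± 0.14), pentose phosphate (0.49), peroxisome (-0.2), fatty acid synthesis (-0.21, with a mean of 0.3), unfolded protein response (-0.04), pro-apoptotic (0.24), anti-apoptotic (-0.93), heat shock (0.72) and autophagy and lysosome genes (-0.24), each given with its median. In all, 9478 of 11885 genes changed, 4809 higher and 4669 lower, and 4124 at least 2-fold. The groups did not overlap for 9355 genes, against 10% by chance. Camera called 21 of 34 lists, of which 5 held with an estimated correlation.

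**Figure D3:**
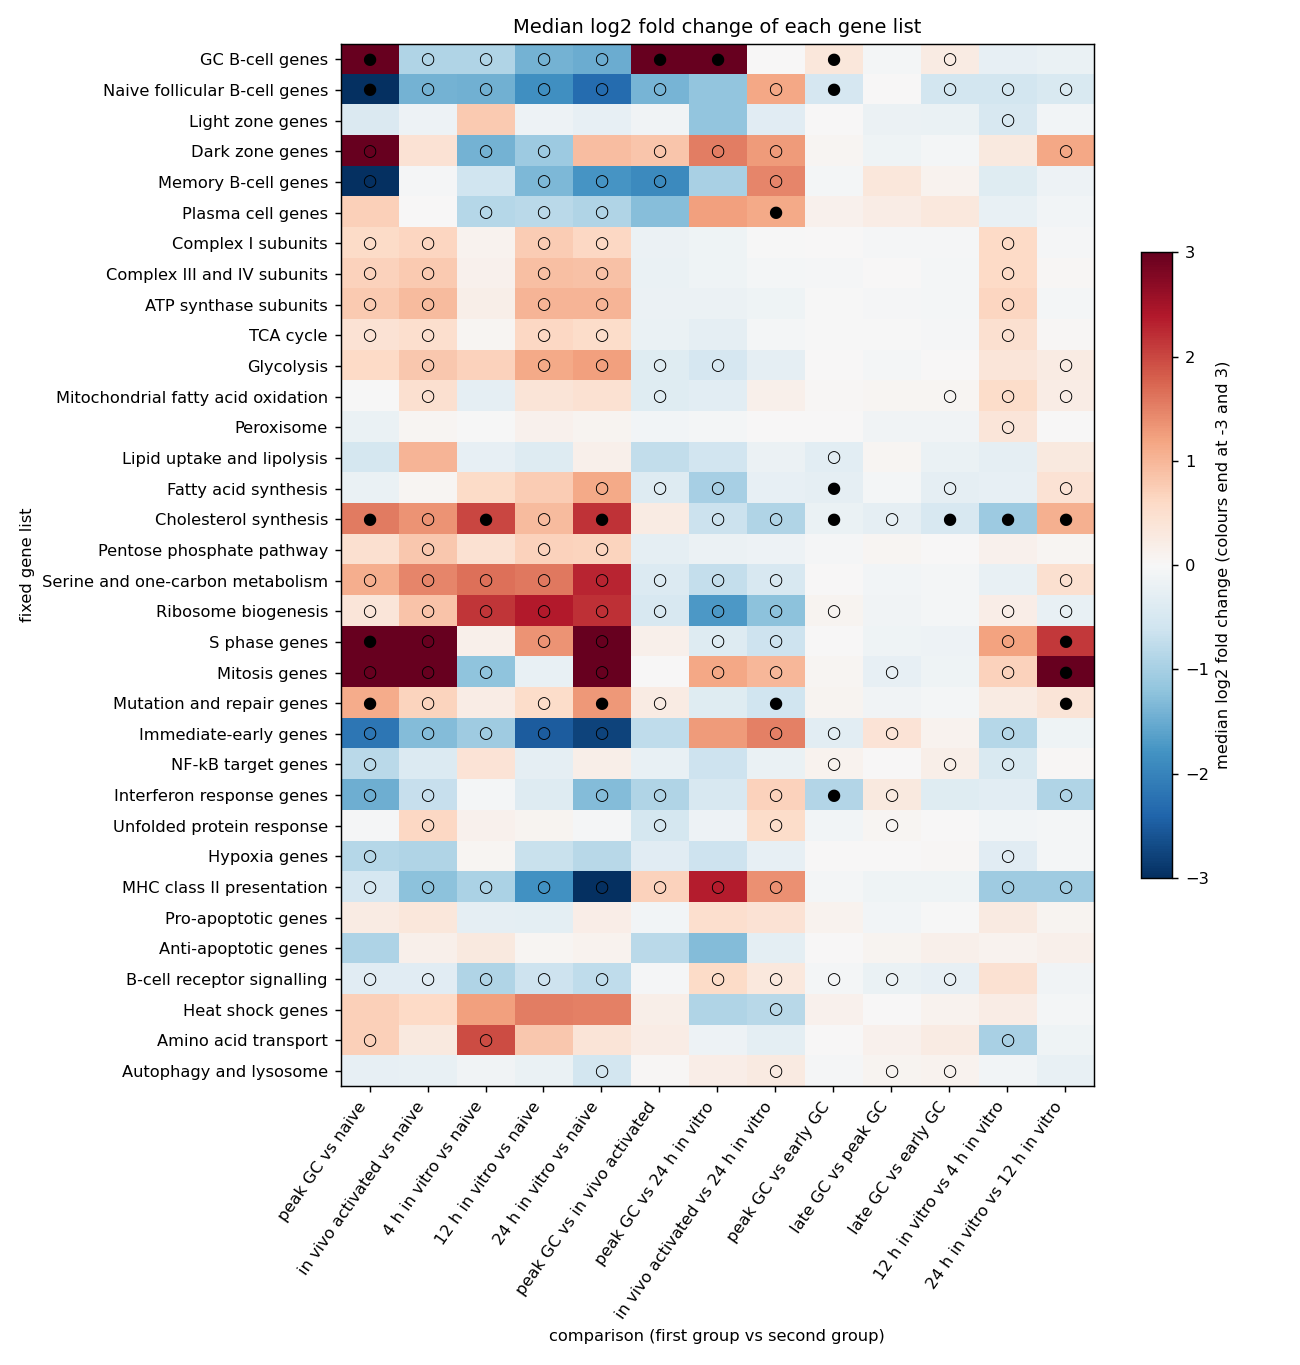
Median log2 fold change of each of the 34 gene lists in the 13 comparisons. Open circles are camera calls, and filled circles are those kept with an estimated correlation.

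Between in vivo activated and naive cells camera called 20 lists, of which 0 held with an estimated correlation. The chemokine gene Ccl22 (8:94745684-94751388) rose from -1.52 ± 0.21 in naive to 7.21 ± 0.82 in in vivo activated cells, a fold change of 8.73 ± 0.48 (adjusted p = 4.14e-12). The ubiquitin-conjugating gene Ube2c rose by 5.81 ± 0.15, Bub1 by 5.69 ± 0.14 and Iqgap3 by 5.78 ± 0.24, all genes of division. The phosphodiesterase gene Pde2a fell from 8.33 ± 0.18 to 2.37 ± 0.21, the calcium channel gene Cacna1i by 5.52 ± 0.20 and Dusp8 by 5.91 ± 0.39 (adjusted p = 4.92e-12). Ddx3y, Eif2s3y and Kdm5d were at the floor in in vivo activated cells. Of the GC B-cell genes 12 of 16 fell and 3 rose (15 adjusted over the list alone, median -0.91, adjusted p = 0.00886, and adjusted p = 0.147 with an estimated correlation), with Neil1 down by 2.08 ± 0.07 and Mef2b up by 3.25 ± 0.12. Naive follicular genes fell in 13 of 15 cases (median -1.42, Cd55 by 3.18 ± 0.10, Il4ra by 1.93 ± 0.08), while Cd38 rose by 0.73 ± 0.11, adjusted p = 0.147 with an estimated correlation. All 12 MHC class II genes fell (12 adjusted over the list alone, median -1.22, H2-DMb1 by 2.31 ± 0.11, adjusted p = 0.202 with an estimated correlation).

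All 29 mitosis genes rose (median 5.1, Ccna2 by 5.34 ± 0.10), as did 29 of 30 S phase genes (median 3.06, Uhrf1 by 4.63 ± 0.05), all 22 cholesterol genes (median 1.35, Sqle by 2.12 ± 0.07) and 28 of 30 ribosome biogenesis genes (median 0.85, Npm1 by 1.74 ± 0.06). Their calls were lost at adjusted p = 0.147, 0.105, 0.0776 and 0.277 with an estimated correlation. ATP synthase genes rose in 15 of 15 cases (median 0.96, Atp5g3 by 1.43 ± 0.05), complex I in 32 of 35 (median 0.64) and the TCA cycle in 16 of 19 (median 0.5, Sdhd by 2.06 ± 0.06, Fh1 by 1.5 ± 0.06). Those lists had adjusted p = 0.202, 0.332 and 0.221 with an estimated correlation. Fatty acid oxidation genes rose in 14 of 21 cases (median 0.49, Acadl by 1.82 ± 0.05) while Cpt1a fell by 0.95 ± 0.06, and all 7 pentose phosphate genes rose (median 0.8, Tkt by 1.36 ± 0.05), with adjusted p = 0.277 and 0.195 with an estimated correlation. Unfolded protein genes rose in 16 of 22 cases (median 0.63, Sdf2l1 by 1.69 ± 0.07, adjusted p = 0.277 with an estimated correlation), and the secretory gene Derl3 rose by 3.54 ± 0.12. Immediate-early genes fell in 13 of 20 cases (median -1.3, Jund by 2.22 ± 0.07), but Egr2 rose by 2.20 ± 0.21 and Egr1 by 1.62 ± 0.24, adjusted p = 0.403 with an estimated correlation. Of 11885 genes, 9424 changed, 4662 higher and 4762 lower, and 3985 at least 2-fold. Groups did not overlap for 9784 genes, against 10% by chance. No marker list was called: NK markers were lower in 7 of 7 (median -3.48, adjusted p = 0.0629), neutrophil in 6 of 8 (-3.61, 0.171), platelet in 3 of 3 (-2.73, 0.114) and T-cell markers in 6 of 10 (-2.12, 0.308).

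After 4 h in vitro, genes of cholesterol synthesis were higher than in naive cells. Gng4, a G protein subunit gene, rose from -4.8 ± 1.49 to 5.29 ± 0.2, the secreted factor gene Spp1 by 7.12 ± 0.16 and the interleukin receptor genes Il1r1 by 6.07 ± 0.65 and Il2ra by 5.84 ± 0.25 (adjusted p = 8.39e-15 for Il2ra). The amino acid transporter gene Slc1a4 rose by 6.36 ± 0.25. Fos fell by 4.96 ± 0.36, from 8.85 ± 0.41 in naive cells, Fosb by 4.96 ± 0.27 from 9.91 ± 0.2, and Plaur by 4.83 ± 0.33 (adjusted p = 6.76e-11). The erythroid gene Slc4a1 fell by 4.95 ± 0.48, and 12 of 13 macrophage markers fell (median -2.95, adjusted p = 0.0389, and adjusted p = 0.374 with an estimated correlation). Plasma cell markers fell in 5 of 7 (median -1.88, adjusted p = 0.34 with an estimated correlation) and marginal zone markers in 9 of 10 (median -1.36, adjusted p = 0.0345 with an estimated correlation). All 30 ribosome biogenesis genes rose (30 adjusted over the list alone, median 2.14, adjusted p = 9.07e-16), such as Nolc1 by 2.37 ± 0.06 and Dkc1 by 2.35 ± 0.06, with adjusted p = 0.258 with an estimated correlation. Cholesterol genes rose in 21 of 22 cases (21 adjusted over the list alone, median 2, adjusted p = 4.30e-10, and 0.027 with an estimated correlation), Sqle by 3.96 ± 0.07 and Cyp51 by 3.31 ± 0.07. This was the 1 list kept among 12 called by camera.

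Serine and one-carbon genes rose in 10 of 14 cases (median 1.65, Psat1 by 3.72 ± 0.07, Shmt1 by 3.52 ± 0.09) and amino acid transporters in 8 of 11 (median 1.96, Slc1a5 by 2.28 ± 0.05), with adjusted p = 0.307 and 0.258 with an estimated correlation. Mitosis genes fell in 23 of 29 cases (median -1.2, Mki67 by 2.59 ± 0.11), dark zone genes in 10 of 12 (median -1.41, Foxo1 by 1.74 ± 0.05), plasma cell genes in 10 of 13 (median -0.85, Mzb1 by 1.99 ± 0.05) and B-cell receptor signalling genes in 21 of 25 (median -0.9). Their calls were lost at adjusted p = 0.483, 0.258, 0.258 and 0.483 with an estimated correlation. Glycolysis was not called (median 0.7, adjusted p = 0.0558). Ldha rose by 2.68 ± 0.06 and Pfkp by 1.94 ± 0.06. Neither was fatty acid oxidation (median -0.26, adjusted p = 0.0792). Cpt1a fell by 1.88 ± 0.06. Lipid uptake genes moved both ways: Fabp5 rose by 3.54 ± 0.12, while Cd36 fell by 2.75 ± 0.14. The list's median (-0.24) and mean (0.32) differ in sign. In total 9269 of 11885 genes changed, 4627 higher and 4642 lower, and 4010 at least 2-fold, with no overlap of groups for 9700 genes against 10% by chance.

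Between 12 h in vitro and naive cells camera called 19 lists, of which 0 held with an estimated correlation. Ccl22 rose from -1.52 ± 0.21 to 5.72 ± 0.17, the transaminase gene Bcat1 by 6.15 ± 0.11, Il2ra by 6.13 ± 0.25, the inhibitory receptor gene Pdcd1 by 5.86 ± 0.24 and Tacc2 by 6.28 ± 0.30 (adjusted p at most 5.89e-11). The transcription factor genes Klf4 and Hes1 fell from 8.57 ± 0.16 to 2.37 ± 0.19 and from 7.19 ± 0.06 to 1.49 ± 0.09. The insulin receptor substrate gene Irs2 fell by 5.32 ± 0.17 from 10.06 ± 0.16 and Fosb fell by 5.64 ± 0.27. Slc4a1 fell by 5.70 ± 0.48, beside 4 of 4 erythroid markers (median -5.11, adjusted p = 0.031, and adjusted p = 0.272 with an estimated correlation) and 11 of 13 macrophage markers (median -3.77, adjusted p = 0.0221, and adjusted p = 0.272 with an estimated correlation). All 30 ribosome biogenesis genes rose (30 adjusted over the list alone, median 2.38, Npm1 by 2.70 ± 0.06), and S phase genes rose in 26 of 30 cases (29 changed adjusted over the list alone, median 1.34, Mcm6 by 2.50 ± 0.05, Cdca7 by 3.22 ± 0.06) while Cdt1 fell by 0.97 ± 0.08. Both had adjusted p = 0.214 with an estimated correlation. Mitosis genes were not called (6 of 29 rose, 13 fell, median -0.22, adjusted p = 0.161).

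Complex I genes rose in 29 of 35 cases (median 0.76, Ndufb6 by 1.77 ± 0.08), complexes III and IV in 19 of 21 (median 0.91, Uqcrq by 1.66 ± 0.06, while Cox7a2l fell by 1.40 ± 0.07), ATP synthase in 14 of 15 (median 1.01, Atp5g3 by 1.64 ± 0.05) and the TCA cycle in 18 of 19 (median 0.63, Sdhd by 1.94 ± 0.06). The calls had adjusted p = 0.404, 0.369, 0.214 and 0.214 with an estimated correlation. Glycolysis genes rose in 15 of 22 cases (median 1.14, Pfkp by 2.41 ± 0.06, adjusted p = 0.404 with an estimated correlation), and cholesterol genes in 21 of 22 (median 0.94, adjusted p = 0.139 with an estimated correlation). The fatty acid oxidation list was not called (median 0.38, adjusted p = 0.512), and Cpt1a, which admits fatty acids to mitochondria, fell by 2.72 ± 0.06. MHC class II genes fell in 12 of 12 cases (12 adjusted over the list alone, median -1.82, H2-DMb2 by 2.86 ± 0.08), immediate-early genes in 16 of 20 (median -2.5, Junb by 3.15 ± 0.12), naive follicular genes in 14 of 15 (median -1.85, Cr2 by 3.69 ± 0.13) and B-cell receptor signalling genes in 20 of 25 (median -0.62, Cd22 by 2.15 ± 0.08). Those calls went to adjusted p = 0.214, 0.216, 0.139 and 0.361 with an estimated correlation. Among memory genes, 9 of 12 of which fell, Zbtb32 rose by 4.26 ± 0.16 and Cd44 by 1.74 ± 0.08. The survival gene Bcl2l1 rose by 4.29 ± 0.09, although NF-kB targets were not called (median -0.27, adjusted p = 0.603). Changed genes numbered 9618 of 11885, 4956 higher and 4662 lower, and 4624 at least 2-fold, with no overlap of groups for 10114 against 10% by chance. T-cell, NK and plasma cell markers fell in 9 of 10, 7 of 7 and 5 of 7 cases (medians -2.65, -3.33 and -0.82, adjusted p = 0.311, 0.272 and 0.272 with an estimated correlation), and marginal zone markers in 9 of 10 (median -2.31, adjusted p = 0.00541 with an estimated correlation).

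At 24 h in vitro, genes of cholesterol synthesis and of mutation and repair were higher than in naive cells. Ccl22 had 8.01 ± 0.08, a rise of 9.53 ± 0.48, the ligand gene Tnfsf14 rose by 8.76 ± 0.38 and the replication gene Mcm10 by 6.30 ± 0.08 (adjusted p = 4.56e-25). The kinase gene Plk2 fell from 8.75 ± 0.29 to 1.25 ± 0.33 and Osgin1 by 6.98 ± 0.29. Aqp1 was at the floor at 24 h, and the NK cell and erythroid markers Gzma and Slc4a1 were near it. All 7 NK markers and all 4 erythroid markers fell (medians -5.05 and -6.94, adjusted p = 0.265 for both with an estimated correlation). Macrophage and plasma cell markers fell in 11 of 13 and 5 of 7 (medians -3.76 and -0.91, adjusted p = 0.29 and 0.265 with an estimated correlation), and marginal zone markers in 10 of 10 (median -2.59, adjusted p = 0.0048 with an estimated correlation). Mitosis genes rose in 28 of 29 cases (28 adjusted over the list alone, median 3.84, Cdk1 by 5.60 ± 0.13) and S phase genes in 29 of 30 (30 changed adjusted over the list alone, median 3.76, Uhrf1 by 5.30 ± 0.05, Mcm6 by 4.48 ± 0.05). Their calls had adjusted p = 0.226 and 0.0858 with an estimated correlation. Mutation and repair genes rose in 18 of 23 cases (median 1.31, Ung by 3.89 ± 0.08) and cholesterol genes in 22 of 22 (22 adjusted over the list alone, median 2.17, Sqle by 3.48 ± 0.07). These were the 2 of 22 called lists that held, both at adjusted p = 0.0321 with an estimated correlation.

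Fatty acid synthesis genes rose in 11 of 14 cases (median 1.14): the desaturase genes Fads1 by 4.84 ± 0.08 and Fads2 by 5.72 ± 0.17, while Scd1 fell by 1.57 ± 0.06 (adjusted p = 0.239 with an estimated correlation). Glycolysis genes rose in 16 of 22 cases (median 1.22, Pfkp by 2.73 ± 0.06, adjusted p = 0.326 with an estimated correlation), and ribosome biogenesis in 30 of 30 (median 2.2, Npm1 by 2.62 ± 0.06, adjusted p = 0.226 with an estimated correlation). Respiratory lists rose again: complex I in 28 of 35 cases (median 0.62), complexes III and IV in 19 of 21 (0.89), ATP synthase in 14 of 15 (1.01) and the TCA cycle in 18 of 19 (0.54), with adjusted p = 0.438, 0.343, 0.239 and 0.239 with an estimated correlation. All 12 MHC class II genes fell (12 adjusted over the list alone, median -3.04, H2-DMb2 by 4.12 ± 0.08, H2-Eb1 by 2.65 ± 0.06, adjusted p = 0.226 with an estimated correlation). Naive follicular genes fell in 15 of 15 cases (median -2.31, Cd55 by 3.91 ± 0.10, adjusted p = 0.0595 with an estimated correlation). GC B-cell genes fell in 11 of 16 cases (median -1.49, Neil1 by 2.99 ± 0.07, adjusted p = 0.226 with an estimated correlation), with Rgs13 up by 2 ± 0.14. Plasma cell genes fell in 9 of 13 cases (median -0.91, Prdm1 by 5.31 ± 0.19), interferon genes in 22 of 25 (24 changed either way, 24 adjusted over the list alone, median -1.3, Irf7 by 3.64 ± 0.14) and lysosome genes in 17 of 24 (median -0.54). Those 3 lists had adjusted p = 0.226, 0.334 and 0.334 with an estimated correlation. Fatty acid oxidation (median 0.45, adjusted p = 0.223) was not called. Acadl rose by 1.57 ± 0.05 and Cpt1a fell by 2.80 ± 0.06. The count was 10074 changed genes of 11885, 5018 higher and 5056 lower, and 5547 at least 2-fold. No overlap of groups was seen for 10307, against 10% by chance.

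**Figure D4:**
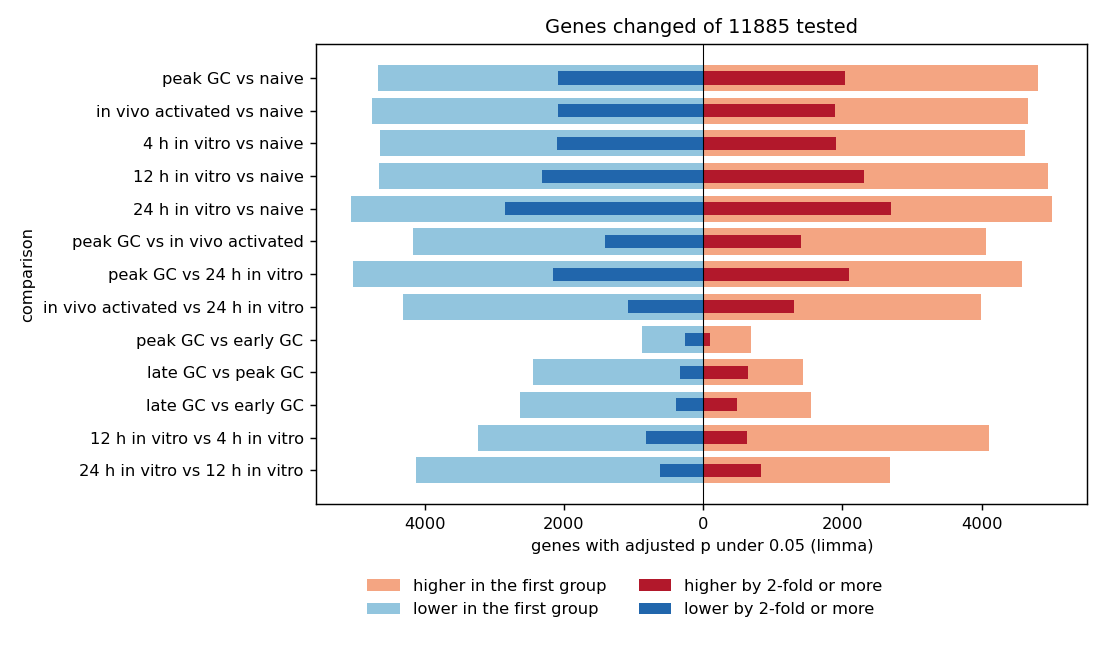
Genes changed in each of the 13 comparisons, of 11885 tested. Wide bars are all genes with adjusted p under 0.05 (limma) and narrow bars those changed at least 2-fold.

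Peak GC cells had more RNA of GC genes than in vivo activated cells, while the lists of division genes were not called. Nuggc, a GC-associated GTPase gene, was higher in peak GC cells by 10.70 ± 0.30 (8.2 ± 0.28 against -2.49 ± 0.73) and Gcsam by 10.49 ± 0.28 (adjusted p = 7.14e-19). The atypical chemokine receptor gene Ccrl1 and the transcription factor gene Tox2 had 4.21 ± 0.23 and 4.51 ± 0.34 in peak GC cells against -4.54 ± 1.25 and -4.54 ± 1.39. The phosphatase gene Alpl was lower by 8.60 ± 0.18 (-1.98 ± 0.29 against 6.62 ± 0.16), Tmem154 was lower by 8.40 ± 0.27, the receptor gene Slamf9 was lower by 7.76 ± 0.25 and the signalling gene Wnt10a was lower by 7.67 ± 0.43 (adjusted p = 1.71e-12). Of the GC B-cell genes 15 of 16 were higher and Lmo2 was lower (16 changed adjusted over the list alone, median 4.94, adjusted p = 1.84e-12, and 2.54e-04 with an estimated correlation), with Basp1 up by 8.14 ± 0.11, S1pr2 by 7.43 ± 0.10 and Neil1 by 5.23 ± 0.07. This list was the 1 of 13 called that held. Memory genes were lower in 10 of 12 cases (median -1.92, Ccr6 by 6.48 ± 0.14, Cd38 by 5.53 ± 0.11), though Nt5e was higher by 5.58 ± 0.22. Naive follicular genes were lower in 12 of 15 (median -1.39, Bcl2 by 4.72 ± 0.11). Both had adjusted p = 0.13 with an estimated correlation. Dark zone genes were higher in 7 of 12 cases (8 changed adjusted over the list alone, median 0.83, adjusted p = 0.364 with an estimated correlation).

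Of the metabolic lists, fatty acid oxidation was lower in peak GC than in in vivo activated cells in 14 of 21 genes (15 changed adjusted over the list alone, median -0.36, adjusted p = 0.00579, and adjusted p = 0.357 with an estimated correlation). Eci2 fell by 1.39 ± 0.07, Decr1 by 1.17 ± 0.08 and Acadl by 1.16 ± 0.05, while Cpt1a rose by 1.47 ± 0.06. The fatty acid carrier gene Cd36 was lower by 5.68 ± 0.14 and the lipid droplet gene Plin3 by 1.41 ± 0.09, in a list that was not called (median -0.74, adjusted p = 0.0867). Glycolysis genes were lower in 12 of 22 cases (median -0.37, Pfkfb3 by 1.21 ± 0.07), fatty acid synthesis genes in 9 of 14 (median -0.39, Scd2 by 2.38 ± 0.14) and ribosome biogenesis genes in 26 of 30 (median -0.47, Dkc1 by 0.74 ± 0.06). These calls went to adjusted p = 0.596, 0.539 and 0.58 with an estimated correlation. The respiratory lists were not called: complex I (median -0.18, adjusted p = 0.1), complexes III and IV (median -0.21, adjusted p = 0.109), ATP synthase (median -0.18, adjusted p = 0.109) and the TCA cycle (median -0.19, adjusted p = 0.0973). Unfolded protein genes were lower in 14 of 22 cases (median -0.53, Pdia4 by 4.03 ± 0.07, Hsp90b1 by 2.44 ± 0.08, adjusted p = 0.357 with an estimated correlation) and interferon genes in 17 of 25 (median -0.9, Ddx58 by 3.12 ± 0.12, with Irf7 higher by 3.20 ± 0.14, adjusted p = 0.582 with an estimated correlation). MHC class II genes were higher in 11 of 12 (median 0.69, H2-Ob by 1.24 ± 0.08), with Ctss lower by 1 ± 0.04, and adjusted p = 0.58 with an estimated correlation. Mitosis (median 0.01, adjusted p = 0.509) and S phase genes (median 0.16, adjusted p = 0.145) were not called. Neutrophil markers were higher in 8 of 8 cases (median 3.3, adjusted p = 0.021, and adjusted p = 0.413 with an estimated correlation) and NK markers in 6 of 7 (3.84, adjusted p = 0.021, and adjusted p = 0.244 with an estimated correlation). Erythroid (4 of 4, median 3.26) and platelet markers (3 of 3, 1.2) were also higher, and stroma (3 of 3, -1.77) and marginal zone markers (6 of 10, -0.82) lower, each at adjusted p = 0.244 with an estimated correlation. A total of 8223 genes changed, 4058 higher and 4165 lower, and 2804 at least 2-fold. Groups did not overlap for 8306 of 11885, against 10% by chance.

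Against cells 24 h in vitro, peak GC cells again had more RNA of GC genes. Nuggc was higher by 9.86 ± 0.30. Gcnt3, Aqp1 and the NK cell marker Gzmb were at the floor at 24 h. Ddx3y, Eif2s3y and Kdm5d were at the floor in peak GC cells. Pdcd1 was lower by 8.59 ± 0.24 (-1.85 ± 0.41 against 6.74 ± 0.08), Tacc2 by 8.31 ± 0.30 and Tmem154 by 7.61 ± 0.27 (adjusted p = 3.06e-16). GC B-cell genes were higher in 15 of 16 cases (16 changed adjusted over the list alone, median 5.14, adjusted p = 1.55e-09, and 0.00138 with an estimated correlation), the 1 list of 11 called that held. Dark zone genes were higher in 11 of 12 (median 1.54, Foxo1 by 2.23 ± 0.05) and mitosis genes in 26 of 29 (median 1.16, Ccnb2 by 3.04 ± 0.11), while S phase genes were lower in 19 of 30 (median -0.38, Ung by 1.43 ± 0.08). These had adjusted p = 0.225, 0.536 and 0.578 with an estimated correlation. MHC class II genes were higher in 11 of 12 (11 adjusted over the list alone, median 2.36, H2-DMa by 3.16 ± 0.08) and B-cell receptor signalling genes in 19 of 25 (median 0.57, Cd22 by 1.93 ± 0.08), with adjusted p = 0.225 and 0.578 with an estimated correlation. All 30 ribosome biogenesis genes were lower (30 adjusted over the list alone, median -1.73, Polr1b by 2.97 ± 0.10, adjusted p = 0.225 with an estimated correlation).

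Lower in peak GC cells were also 13 of 14 serine and one-carbon genes (median -0.72, Shmt1 by 2.41 ± 0.09), 11 of 14 fatty acid synthesis genes (median -1, Acaca by 1.93 ± 0.10), 17 of 22 cholesterol genes (median -0.65, Lss by 1.5 ± 0.09) and 14 of 22 glycolysis genes (median -0.51, Pfkp was lower by 1.61 ± 0.06). The 4 calls went to adjusted p = 0.502, 0.225, 0.278 and 0.548 with an estimated correlation. Cpt1a was higher by 3.32 ± 0.06 in a fatty acid oxidation list that was not called (median -0.31, adjusted p = 0.202). Plasma cell genes were not called (median 1.23, adjusted p = 0.112). Eaf2 was higher by 7.26 ± 0.10 and Igj by 6.62 ± 0.11. NF-kB targets were not called (median -0.62, adjusted p = 0.0931), with Nfkbie lower by 3.07 ± 0.07 and Lta higher by 4.23 ± 0.16. For unfolded protein genes the median (-0.15) and mean (0.1) differ in sign. Macrophage, NK and erythroid markers were higher in 11 of 13, 6 of 7 and 4 of 4 cases (medians 3.85, 5.12 and 8.59), with adjusted p = 0.387, 0.377 and 0.377 with an estimated correlation. Genes changed numbered 9614, 4579 higher and 5035 lower, and 4249 at least 2-fold. There was no overlap of groups for 9502 of 11885, against 10% by chance.

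In vivo activated cells had more RNA of plasma cell genes than cells 24 h in vitro, and less of mutation and repair genes. The fatty acid carrier gene Cd36 was higher by 5.71 ± 0.14 (9.67 ± 0.09 against 3.96 ± 0.08), the metallothionein gene Mt2 by 6.53 ± 0.37, the chemokine receptor gene Cxcr3 by 5.27 ± 0.26, Cdh17 by 5.13 ± 0.19 and the complement gene Cfp by 4.90 ± 0.12 (adjusted p at most 5.44e-13). Tnfsf14 was lower by 4.51 ± 0.38, Ifitm2 by 4.48 ± 0.22 and Il2ra was lower by 4.45 ± 0.25 (3.08 ± 0.32 against 7.52 ± 0.12). The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were at the floor in in vivo activated cells. Plasma cell genes were higher in 11 of 13 cases (12 adjusted over the list alone, median 1.13, Prdm1 by 4.65 ± 0.19, Igj by 3.96 ± 0.11, Derl3 by 3.63 ± 0.12), and mutation and repair genes lower in 20 of 23 (21 changed adjusted over the list alone, median -0.59, Ung by 1.35 ± 0.08, Msh6 by 1.28 ± 0.06). These were the 2 of 17 called lists that held, both at adjusted p = 0.0337 with an estimated correlation. Marginal zone markers were higher in 10 of 10 cases (median 2.04, adjusted p = 7.53e-04 with an estimated correlation). Macrophage, erythroid, stroma and plasma cell markers were higher in 12 of 13, 4 of 4, 3 of 3 and 5 of 7 (medians 3.34, 5.89, 1.96 and 1.86), with adjusted p = 0.258, 0.175, 0.227 and 0.172 with an estimated correlation.

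All 12 MHC class II genes were higher (12 adjusted over the list alone, median 1.38, H2-DMb2 by 2.52 ± 0.08), as were 16 of 22 unfolded protein genes (median 0.55, Pdia4 by 1.19 ± 0.07), 12 of 15 naive follicular genes (median 1.16, Cd38 by 2.50 ± 0.11) and 9 of 12 memory genes (median 1.46, Tle3 by 1.53 ± 0.08). All 30 ribosome biogenesis genes were lower (30 adjusted over the list alone, median -1.24, Polr1b by 2.23 ± 0.10), as were 17 of 22 cholesterol genes (median -0.9, Hmgcs1 by 1.90 ± 0.07). Each of these 6 lists had adjusted p = 0.0827 with an estimated correlation. Mitosis genes were higher in 26 of 29 (median 1, Ccnb2 by 2.72 ± 0.11), immediate-early genes in 16 of 20 (median 1.51, Zfp36 by 3.08 ± 0.15) and dark zone genes in 9 of 12 (median 1.27, Foxo1 by 1.28 ± 0.05), while S phase genes were lower in 26 of 30 (median -0.61, Cdca7 by 1.32 ± 0.06). They had adjusted p = 0.239 for immediate-early and S phase genes, 0.287 for mitosis and 0.202 for dark zone genes with an estimated correlation. B-cell receptor signalling genes were higher in 19 of 25 (median 0.32, Fcgr2b by 1.90 ± 0.05), interferon genes in 16 of 25 (0.69, Ddx58 by 1.75 ± 0.12) and lysosome genes in 15 of 24 (0.28). Lower were 10 of 14 serine and one-carbon genes (-0.49, Shmt1 by 1.59 ± 0.09) and 9 of 14 heat shock genes (-0.83, Hspd1 by 1.25 ± 0.07). These had adjusted p = 0.382, 0.517, 0.382, 0.382 and 0.382 with an estimated correlation. Fatty acid oxidation was not called (median 0.16, adjusted p = 0.243), with Cpt1a higher by 1.85 ± 0.06, and neither were glycolysis (median -0.28, adjusted p = 0.0761) or GC B-cell genes (median 0.01, adjusted p = 0.492). Genes changed numbered 8300, 3988 higher and 4312 lower, and 2390 at least 2-fold. Groups did not overlap for 9008 of 11885, against 10% by chance.

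Among GC stages, peak GC cells had less RNA of interferon response and naive B-cell genes than early GC cells. The lipid-binding gene Osbpl3 rose by 3.27 ± 0.24 (3.74 ± 0.14 against 0.47 ± 0.15), Etl4 by 2.94 ± 0.29 and Tox2 by 2.50 ± 0.79 (adjusted p = 0.0397 for Tox2). The lipid kinase gene Pip5k1b fell by 2.12 ± 0.10 (adjusted p = 1.77e-12), Rgs18 fell by 1.95 ± 0.18, Cd36 by 1.91 ± 0.14 (3.98 ± 0.18 against 5.89 ± 0.15), Lgals9 by 1.69 ± 0.12 and Cd38 fell by 1.61 ± 0.11. Interferon response genes fell in 18 of 25 cases (20 adjusted over the list alone, median -0.87, adjusted p = 4.53e-15, and 0.0385 with an estimated correlation): Cmpk2 by 1.40 ± 0.18, Ddx58 by 1.14 ± 0.12, Oasl1 by 1.11 ± 0.14 and Ifit2 by 0.84 ± 0.11. Naive follicular genes fell in 9 of 15 (9 adjusted over the list alone, median -0.51, adjusted p = 1.34e-11, and 0.00805 with an estimated correlation), with Ccr6 down by 1.52 ± 0.14 and Bcl2 by 0.98 ± 0.11. GC B-cell genes rose in 8 of 16 and 1 fell (9 adjusted over the list alone, median 0.33, adjusted p = 8.83e-05, and 0.0292 with an estimated correlation), among them Basp1 by 1.26 ± 0.11 and Rgs13 by 0.92 ± 0.14. Fatty acid synthesis genes fell in 8 of 14 (11 adjusted over the list alone, median -0.26, Scd2 by 1.10 ± 0.14, Scd1 by 0.43 ± 0.06) and cholesterol genes in 8 of 22 (13 adjusted over the list alone, median -0.21, Fdps by 0.34 ± 0.06), both at adjusted p = 0.0474 with an estimated correlation.

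Further calls did not hold. Lipid uptake genes fell in 5 of 14 (8 adjusted over the list alone, median -0.32, Lipa by 0.39 ± 0.08, adjusted p = 0.219 with an estimated correlation), and immediate-early genes in 5 of 20 (median -0.31, Ier2 by 0.59 ± 0.09, adjusted p = 0.547 with an estimated correlation). NF-kB targets rose in 5 of 24 (median 0.11, Ebi3 by 0.86 ± 0.13, adjusted p = 0.547 with an estimated correlation) and ribosome biogenesis genes in 2 of 30 (1 adjusted over the list alone, median 0.09, Npm1 by 0.19 ± 0.06), while B-cell receptor signalling genes fell in 2 of 25 (median -0.06, Cd72 by 0.38 ± 0.08), both at adjusted p = 0.742 with an estimated correlation. Complex I (median 0, adjusted p = 0.765), mitosis (median 0.06, adjusted p = 0.453) and fatty acid oxidation genes (median 0.03, adjusted p = 0.332) were not called, although Acadl rose by 0.25 ± 0.05. Macrophage markers were lower as a list (median -0.8, although 1 of 13 passed alone, adjusted p = 0.0018, and adjusted p = 0.255 with an estimated correlation), as were erythroid markers (median -1.34, adjusted p = 0.0184, and adjusted p = 0.255 with an estimated correlation) and marginal zone markers (median -0.61, 4 of 10, adjusted p = 9.86e-05, and 0.00286 with an estimated correlation). In this comparison 1568 genes changed, 686 higher and 882 lower, and 361 at least 2-fold. With only both stages fitted 610 changed, and 1034 without early GC replicate 2. No overlap of groups was seen for 2870 of 11885 genes, against 10% by chance. Camera called 10 of 34 lists and 5 held with an estimated correlation.

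Late GC cells differed from peak GC cells in genes that include many markers of other blood cells. The calgranulin gene S100a9 rose by 2.90 ± 0.57 (5.68 ± 1.47 against 2.78 ± 1.11). This SE, pooled over groups, understates that spread. Fn1 rose by 2.76 ± 0.47, Ccl6 by 2.74 ± 0.83, Ccl9 by 2.6 ± 0.36, Lrp1 by 2.85 ± 0.23 and Ahnak by 2.70 ± 0.14 (all adjusted p at most 0.0158). Neutrophil markers were higher in 8 of 8 cases (median 2.69, adjusted p = 3.90e-06, and adjusted p = 0.138 with an estimated correlation). Macrophage markers were higher in 7 of 13 (1.45, adjusted p = 3.18e-06, and adjusted p = 0.0511 with an estimated correlation) and erythroid markers in 4 of 4 (2.21, adjusted p = 4.39e-04, and adjusted p = 0.0511 with an estimated correlation). T-cell and NK markers were higher in 2 of 10 and 2 of 7 (medians 1.07 and 0.84, adjusted p = 0.214 and 0.212 with an estimated correlation). Marginal zone markers were higher in 6 of 10 (median 0.69, adjusted p = 0.00337 with an estimated correlation), while dendritic (0.62, adjusted p = 0.0541), plasma cell (median 0.22, adjusted p = 0.066), platelet (median 0.06, adjusted p = 0.406) and stroma markers (median 0, adjusted p = 0.812) were not called. Lyz2, a macrophage and neutrophil gene, had 9.54 ± 1.15 in late, 6.97 ± 0.7 in peak and 7.25 ± 0.59 in early GC cells, against 4.28 ± 0.32 in naive and 2.66 ± 0.54 in in vivo activated cells. Late GC replicate 1 had the highest neutrophil score of the GC libraries, 4.97. Lower in late GC cells were the transporter genes Slco4a1 by 1.57 ± 0.20 and Slc30a4 by 1.01 ± 0.12, and the collagen gene Col11a2 by 1.14 ± 0.15 (adjusted p at most 9.42e-05).

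**Figure D5:**
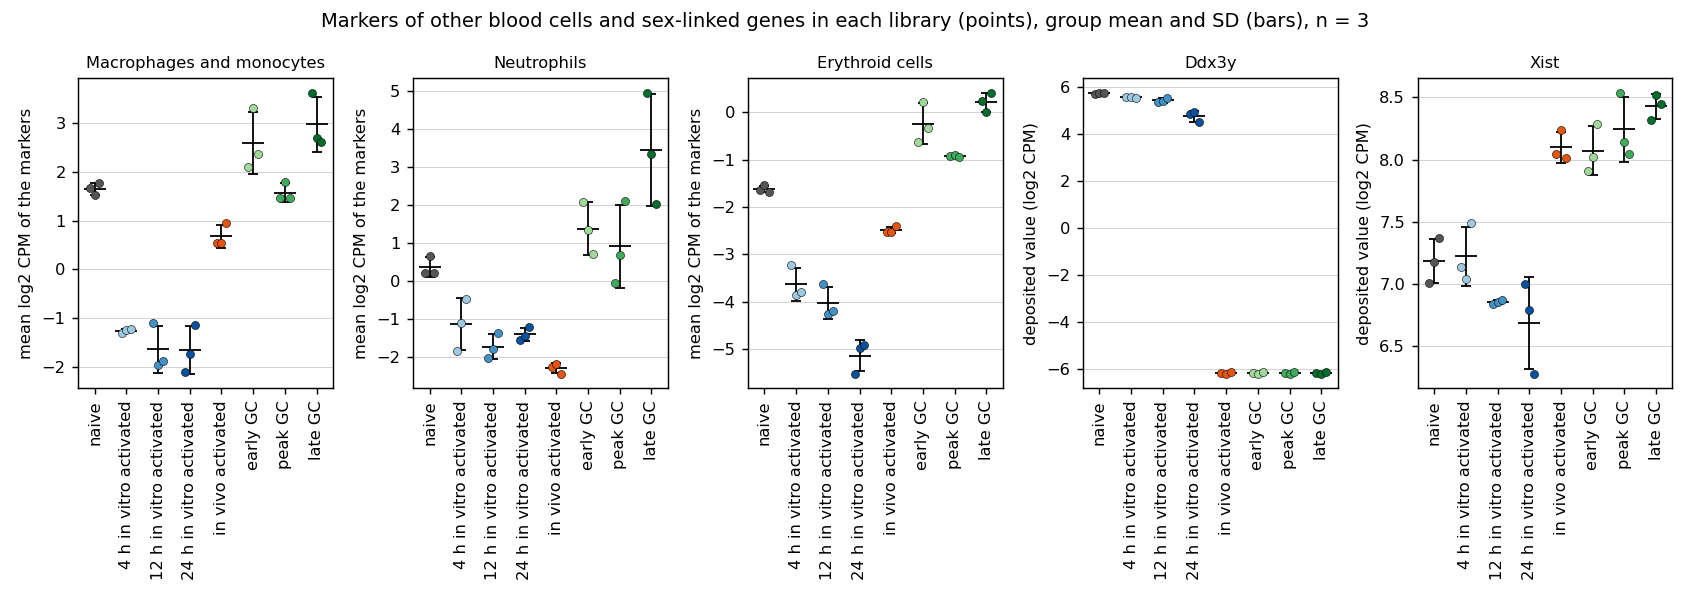
Marker scores of macrophages, neutrophils and erythroid cells and values of Ddx3y and Xist in each library. Points are libraries, and bars are the group mean and SD (n = 3).

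Immediate-early genes were higher in late than in peak GC cells in 11 of 20 cases (14 changed adjusted over the list alone, median 0.41, Ier3 by 2.03 ± 0.37, Atf3 by 1.95 ± 0.35, Fosl2 by 1.71 ± 0.20), interferon genes in 10 of 25 (14 changed adjusted over the list alone, median 0.3, Ifih1 by 0.98 ± 0.18, with Stat2 lower by 0.52 ± 0.12) and lysosome genes in 7 of 24 (7 adjusted over the list alone, median 0.08, Ctsl by 1.48 ± 0.22, Ctsd by 0.96 ± 0.11). They had adjusted p = 0.554, 0.554 and 0.453 with an estimated correlation. Unfolded protein genes rose in 6 of 22 (median 0.07, Pdia4 by 0.37 ± 0.07, adjusted p = 0.554 with an estimated correlation). Cholesterol genes fell in 14 of 22 (18 adjusted over the list alone, median -0.28, Lss by 0.54 ± 0.09), B-cell receptor signalling genes in 13 of 25 (15 changed adjusted over the list alone, median -0.2, Cd72 by 0.50 ± 0.08, Btk by 0.33 ± 0.05) and mitosis genes in 8 of 29 (5 adjusted over the list alone, median -0.24, Aurkb by 0.34 ± 0.09). Those calls had adjusted p = 0.453, 0.603 and 0.791 with an estimated correlation. GC B-cell genes were not called (median -0.05, mean 0, adjusted p = 0.732), nor were light zone (median -0.17, adjusted p = 0.732), dark zone (median -0.13, adjusted p = 0.993) or fatty acid oxidation genes (median 0.07, adjusted p = 0.148). Memory genes were not called either (median 0.33, adjusted p = 0.083). Genes changed numbered 3877, 1431 higher and 2446 lower, and 983 at least 2-fold, of which 650 were higher. With only both stages fitted 1207 changed, and with a covariate of other-cell markers 948. That covariate kept 3 of the 7 list calls. The share of higher calls was 36.9% over all libraries as deposited, but 58.6% with only those of both stages, 57% with each library shifted by the trimmed mean of log ratios (2001 higher, 1507 lower) and 55.2% with the median. The largest shift of a library was 0.106 log2. Groups did not overlap for 4302 of 11885 genes, against 10% by chance, and of 7 lists called 0 held with an estimated correlation.

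Between late and early GC cells, Cd38 and cholesterol genes were lower and Osbpl3 was higher. Cd38 fell by 3.52 ± 0.11 (0.25 ± 0.18 against 3.77 ± 0.12, adjusted p = 7.38e-16), the chromatin organizer gene Satb1 by 1.93 ± 0.12, Spp1 by 2.04 ± 0.16, Gpr174 by 2.44 ± 0.22 and Slc30a4 by 2.31 ± 0.12. Osbpl3 rose by 4.72 ± 0.24 (5.19 ± 0.09 against 0.47 ± 0.15), Etl4 by 3.94 ± 0.29 and the receptor gene Bmpr1a by 3.05 ± 0.69 (adjusted p = 0.00209). Cholesterol genes fell in 21 of 22 cases (22 adjusted over the list alone, median -0.48, adjusted p = 2.91e-10, and 0.022 with an estimated correlation), such as Lss by 0.79 ± 0.09, Acat2 by 0.70 ± 0.08 and Fdps by 0.55 ± 0.06. This list was the 1 of 8 called that held. Fatty acid synthesis genes fell in 9 of 14 (11 adjusted over the list alone, median -0.28, Scd2 by 1.27 ± 0.14, adjusted p = 0.276 with an estimated correlation). GC B-cell genes rose in 6 of 16 and 1 fell (median 0.24, Rgs13 by 1.39 ± 0.14, Basp1 by 1.36 ± 0.11, adjusted p = 0.104 with an estimated correlation). Naive follicular genes fell in 9 of 15 (median -0.54, Bank1 by 1.36 ± 0.08, adjusted p = 0.276 with an estimated correlation), while Klf2 rose by 0.97 ± 0.21.

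B-cell receptor signalling genes were lower in late than in early GC cells in 16 of 25 cases (19 changed adjusted over the list alone, median -0.25, Cd72 by 0.87 ± 0.08, Fcgr2b by 0.49 ± 0.05, adjusted p = 0.555 with an estimated correlation). NF-kB targets rose in 11 of 24 (median 0.17, Nfkbiz by 1.09 ± 0.11, Nfkbia by 0.67 ± 0.09), fatty acid oxidation genes in 6 of 21 (9 changed adjusted over the list alone, median 0.05, Hadh by 0.34 ± 0.06, Acadl by 0.30 ± 0.05) and lysosome genes in 8 of 24 (median 0.11, Sqstm1 by 0.56 ± 0.10). All had lost calls, at adjusted p = 0.24, 0.555 and 0.495 with an estimated correlation. Interferon genes were not called (median -0.36, adjusted p = 0.0537), nor were glycolysis (median 0.02, adjusted p = 0.888), with Hk2 up by 0.70 ± 0.11, or lipid uptake genes (median -0.19, adjusted p = 0.483), with Cd36 down by 1.86 ± 0.14. Neutrophil markers rose in 6 of 8 (median 2.24, adjusted p = 3.94e-04, and adjusted p = 0.313 with an estimated correlation). T-cell and NK markers rose in 4 of 10 and 2 of 7 (medians 1.25 and 1.11, adjusted p = 0.313 for both with an estimated correlation). Macrophage markers were not called (adjusted p = 0.0526), and their median (-0.13) and test direction (higher) differ in sign. Of 11885 genes 4169 changed, 1544 higher and 2625 lower, and 868 at least 2-fold. With only both stages fitted 2381 changed. The share of higher calls was 37% as deposited, 43% with only those, 53.1% with the trimmed mean shift and 49.4% with the median shift. There was no overlap of groups for 4842 genes, against 10% by chance.

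From 4 h to 12 h in vitro, genes of cholesterol synthesis fell. The inhibitory receptor genes Pdcd1 and Lag3 rose by 3.51 ± 0.24 and 3.32 ± 0.33, the checkpoint kinase gene Chek1 by 2.70 ± 0.11 and Sirpa by 3.31 ± 0.29 (adjusted p at most 1.35e-08). Spp1 fell by 5.83 ± 0.16 (1.99 ± 0.07 against 7.82 ± 0.14), Gng4 by 4.96 ± 0.76, Fosl2 by 4.05 ± 0.20 and the integrin gene Itga9 by 4.33 ± 0.45. Cholesterol genes fell in 19 of 22 cases (21 changed adjusted over the list alone, median -1.1, Hmgcs1 by 1.51 ± 0.07, adjusted p = 1.93e-10, and 0.0251 with an estimated correlation), the 1 of 17 called lists that held. Complex I genes rose in 34 of 35 (34 adjusted over the list alone, median 0.6, Ndufv1 by 0.84 ± 0.06), complexes III and IV in 21 of 21 (median 0.59, Uqcr11 by 1.02 ± 0.07), ATP synthase in 15 of 15 (median 0.65, Atp5d by 0.94 ± 0.06) and the TCA cycle in 18 of 19 (median 0.49, Fh1 by 1 ± 0.06). They had adjusted p = 0.182, 0.182, 0.127 and 0.127 with an estimated correlation. Fatty acid oxidation genes rose in 18 of 21 (median 0.56, Hadh by 1.33 ± 0.06) while Cpt1a fell by 0.84 ± 0.06, peroxisome genes rose in 17 of 26 (median 0.37, Abcd3 by 0.84 ± 0.08) and S phase genes in 26 of 30 (median 1.21, Cdc45 by 2.21 ± 0.07, Uhrf1 by 2.08 ± 0.05), each at adjusted p = 0.127 with an estimated correlation.

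Amino acid transport genes fell in 10 of 11 (11 adjusted over the list alone, median -0.98, Slc7a1 by 1.98 ± 0.08), MHC class II genes in 11 of 12 (median -1.06, H2-Eb1 by 1.65 ± 0.06), immediate-early genes in 15 of 20 (17 changed adjusted over the list alone, median -0.86, Nr4a2 by 3.08 ± 0.27) and NF-kB targets in 16 of 24 (21 changed adjusted over the list alone, median -0.45, Cd83 by 1.14 ± 0.07, with Ebi3 up by 1.41 ± 0.13). Those calls had adjusted p = 0.123, 0.127, 0.182 and 0.176 with an estimated correlation. Hypoxia genes fell in 9 of 19 (median -0.35, Vegfa by 3.08 ± 0.24), naive follicular genes in 9 of 15 (-0.54, Cr2 by 2.24 ± 0.13) and light zone genes in 7 of 14 (-0.48, Cd86 by 3.49 ± 0.07), with adjusted p = 0.182, 0.182 and 0.253 with an estimated correlation. Mitosis genes rose in 23 of 29 (0.69, Cdk1 by 2.35 ± 0.13, adjusted p = 0.42 with an estimated correlation) and ribosome biogenesis genes in 15 of 30 (0.21, Npm1 by 0.59 ± 0.06, adjusted p = 0.593 with an estimated correlation). Dendritic, NK, T-cell, platelet and marginal zone markers fell in 4 of 6, 6 of 7, 5 of 10, 2 of 3 and 6 of 10 (medians -1.67, -2.18, -1.11, -0.75 and -0.98), with adjusted p = 0.0878, 0.346, 0.469, 0.195 and 0.0878 with an estimated correlation. For anti-apoptotic genes, which were not called, the median (0.1) and the test direction (lower) differ in sign. Genes changed numbered 7351, 4114 higher and 3237 lower, and 1442 at least 2-fold. Groups did not overlap for 8832 of 11885, against 10% by chance.

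From 12 h to 24 h in vitro, genes of division and cholesterol synthesis rose. Ccna2 rose by 5.68 ± 0.10, Mki67 by 5.62 ± 0.11, the nucleotide reductase gene Rrm2 by 5.44 ± 0.08, Birc5 by 5.31 ± 0.11 and the lipoprotein lipase gene Lpl by 6.22 ± 0.44 (adjusted p at most 4.58e-11). The chemokine receptor gene Cxcr4 fell by 3.02 ± 0.33 (4.73 ± 0.64 against 7.75 ± 0.28), Rgs16 by 3.13 ± 0.31 and Itgb3 by 2.11 ± 0.06. All 29 mitosis genes (29 adjusted over the list alone, median 4.48, adjusted p = 2.91e-38, and 0.0135 with an estimated correlation) and all 30 S phase genes rose (30 adjusted over the list alone, median 2.11, Tk1 by 3.36 ± 0.08, adjusted p = 0.00229 with an estimated correlation). Mutation and repair genes rose in 16 of 23 (16 adjusted over the list alone, median 0.38, Lig1 by 3.27 ± 0.05, Brca1 by 3.14 ± 0.06) and cholesterol genes in 22 of 22 (22 adjusted over the list alone, median 1.06, Acat2 by 1.57 ± 0.08), both at adjusted p = 0.00229 with an estimated correlation. These 4 of 13 called lists held.

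Fatty acid synthesis genes rose in 9 of 14 (median 0.44, Fads2 by 4.46 ± 0.17, Scd2 by 2.96 ± 0.14), serine and one-carbon genes in 8 of 14 (0.49, Tyms by 3.70 ± 0.09), fatty acid oxidation genes in 11 of 21 (0.23, Acadl by 1.06 ± 0.05), glycolysis genes in 14 of 22 (18 changed adjusted over the list alone, 0.24, Tpi1 by 0.60 ± 0.07) and dark zone genes in 7 of 12 (1.17, Ccnd3 by 1.90 ± 0.07). They had adjusted p = 0.143, 0.357, 0.357, 0.561 and 0.454 with an estimated correlation. MHC class II genes fell in 12 of 12 (median -1.07, Cd74 by 1.39 ± 0.09), interferon genes in 20 of 25 (-0.91, Irf7 by 2.11 ± 0.14), naive follicular genes in 11 of 15 (-0.46, Cd55 by 1.43 ± 0.10) and ribosome biogenesis genes in 19 of 30 (-0.23, Pes1 by 0.49 ± 0.04), with adjusted p = 0.177, 0.561, 0.26 and 0.765 with an estimated correlation. For light zone, unfolded protein and hypoxia genes, none of them called, the medians (-0.08, -0.05 and -0.05) and the test direction (higher) differ in sign. In this step 6812 genes changed, 2679 higher and 4133 lower, and 1449 at least 2-fold. No marker list was called. No overlap of groups was seen for 8393 of 11885, against 10% by chance.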

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

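The tests of differences from 4 h and 12 h cells given here were chosen after the medians against naive cells had been seen. Pairs of groups stood out where a list that camera called in both, each against the same naive libraries, moved in opposite directions, and camera also called the difference between the groups. GC B-cell genes had a median of 4.65 in peak GC cells against naive, but -0.91 in in vivo activated cells and -0.91, -1.41 and -1.49 at 4 h, 12 h and 24 h in vitro. The call held in peak GC cells (0.00728), and the others were lost at adjusted p = 0.147, 0.258, 0.214 and 0.226 with an estimated correlation. Peak GC cells were above in vivo activated cells by a median of 4.94 (adjusted p = 1.84e-12, and 2.54e-04 with an estimated correlation), above 4 h cells by 4.16 (4.01e-09 and 0.00212), above 12 h cells by 4.63 (8.06e-10 and 0.0014) and above 24 h cells by 5.14 (1.55e-09 and 0.00138). Dark zone genes had medians of 4.11 in peak GC cells, -1.41 at 4 h and -1.1 at 12 h, all lost at adjusted p = 0.211, 0.258 and 0.216 with an estimated correlation. Peak GC cells were higher by 5.21 than 4 h cells (5.29e-05, and 0.0876 with an estimated correlation) and by 4.95 than 12 h cells (4.71e-06 and 0.0789). Mitosis genes had medians of 5.28 in peak GC and 5.1 in in vivo activated cells and 3.84 at 24 h, but -1.2 at 4 h, all lost at adjusted p = 0.136, 0.147, 0.226 and 0.483 with an estimated correlation. The differences from 4 h were 6.18 for peak GC (1.49e-17, and 0.102 with an estimated correlation) and 6.36 for in vivo activated cells (5.09e-20 and 0.151), and 4 h minus 24 h was -5.2 (2.07e-20 and 0.164). Pairs share the naive libraries' chance deviations. As opposite calls chose them, these differences are no separate test. The dark zone and mitosis lists share Mki67, Hmmr, Plk1, Cenpf and Ccnb1, so they are not independent. No technical explanation was weighed for these lists.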

How the results depend on the processing

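The depth of the libraries is unknown, so what a value at the floor excludes cannot be given. RLE and upper-quartile factors, DESeq2 and limma-voom need counts and were not run. Leaving out immunoglobulin and T-cell receptor segments moves nothing, since 0 are among the symbols. Of 1797 calls of named genes, 1780 stayed past the threshold in the same direction without a filter on low values, 1650 with only the libraries of both groups, 1767 with the replicate block, 1743 with trimmed mean shifts, 1750 with median shifts, 1787 without variance trend and robust fit, and 1794 with log2 of CPM plus 1. With the filter at 5 CPM 1778 of 1778 tested stayed, and with single libraries left out 10427 of 10782; none reversed in these settings. The last 4 settings of scaling, trend and pseudocount and the covariate below were chosen after the data had been seen.

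With only the libraries of both groups, peak against early GC gave 610 changed genes (1568 over all libraries), late against peak 1207 (3877) and late against early 2381 (4169). The cause was not tested. Leaving out single libraries gave 1034 (without early GC replicate 2) to 1549 for peak against early GC. With the covariate of other-cell markers, peak against early GC gave 1045 and late against peak 948, of which 762 were among the 3877, and 7 lists (2 higher, 5 lower), of which 3 were among the 7 (4 higher, 3 lower) called without it. That covariate is higher in all late than in all peak GC libraries, so there it cannot be told from the stage. Of 345 named calls in the GC comparisons 201 stayed, 139 lost the threshold and 5 reversed, all in late against peak GC: Plin2 -0.064, Acad10 0.07, Slc7a6 0.003, Ltf -0.261 and G6pdx -0.166, all with an adjusted p over the threshold there. The cause was not tested.

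With an estimated correlation camera called 5 of 34 lists for peak GC, 0 for in vivo activated, 1 for 4 h, 0 for 12 h and 2 for 24 h, each against naive. It called 1 for peak GC against in vivo activated, 1 for peak GC against 24 h, 2 for in vivo activated against 24 h, 5 for peak against early, 0 for late against peak, 1 for late against early, 1 for 12 h against 4 h and 4 for 24 h against 12 h. Correlated members widen the spread this test allows for. Fry called 33 lists for peak GC, 33 for in vivo activated, 33 for 4 h and 30 for 12 h against naive, 30 for peak GC against in vivo activated, 33 for peak GC against 24 h, 30 for in vivo activated against 24 h, 10 for peak against early (8 of camera's 10), 8 for late against peak (5 of camera's 7), 16 for late against early, 31 for 12 h against 4 h and 21 for 24 h against 12 h. Fry does not compare a list with other genes.

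Whether the replicate numbers pair the libraries is unknown, as the number means had been removed from the values. With the replicate block, 9308, 9253, 9074, 9420 and 9939 genes changed for peak GC, in vivo activated, 4 h, 12 h and 24 h against naive, 7956 and 9437 for peak GC against in vivo activated and 24 h, 8037 for in vivo activated against 24 h, 1182, 3277 and 3648 for peak against early, late against peak and late against early GC, 6998 for 12 h against 4 h and 6395 for 24 h against 12 h. List counts did not move, except 13 for 4 h against naive.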

Other observations

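The genes of this paragraph and the next were chosen after their values were seen; of the tests further on, those of the library shifts, the GC stage, Xist, immediate-early and heat shock genes and the splits were chosen after the results, while those of other-cell RNA and of X-linked genes were not. A gene is called set apart here where each library of a kind has at least 10 CPM and lies at least 4-fold above each other library. The GC libraries set 48 genes apart. Besides Gcsam (log2 mean 7.70, gap to the next library 6), Nuggc (8.04, 5.66) and S1pr2 (8.64, 5.27), these include Rassf6 (7.10, 5.52), the deaminase gene Ada (7.84, 3.96), Lgr5 (4.68, 3.58), Reln (6.47, 3.32) and the lipase gene Lipc (7.27, 3.13). Early, peak and late GC cells each set 0 apart alone.

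Naive cells set 33 genes apart, among them Hes1 (7.19, 4.25), Abcg1 (7.97, 3.20), Socs3 (8.07, 3.06), Irs2 (10.06, 2.30) and Klf2 (10.64, 2.03). In vivo activated cells set 9 apart, including Cxcr3 (5.27, 4.16), Mt1 (6.80, 3.96) and Cd36 (9.67, 2.12). All in vitro libraries set 3 apart, such as Il2ra (7.82, 3.99), 4 h 11, such as Gng4 (5.29, 4.48) and Spp1 (7.82, 3.68), and 24 h 3: Tnfsf14 (5.47, 2.89), Zap70 (4.89, 2.63) and Lpl (4.37, 2.01).

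Macrophage (7 of 13), neutrophil (8 of 8) and erythroid markers (4 of 4) rose from peak to late GC. An estimated correlation removed these calls. RNA from other blood cells in late GC is a candidate explanation. Over 632 genes at least 2-fold higher there, markers left out, the median correlation with the marker score within groups was 0.55. For 333 at least 2-fold lower it was -0.225. Random sets (1000, at most -0.047) ignore that genes vary together and decide nothing. The median rise of 25 tested markers (2.24) exceeded the largest library shift (0.106). Those shifts come from values already sharing nearly one distribution, so that step was not tested. The score of 33 markers differed by 1.68 between late and peak GC without overlap, so stage and other cells cannot be told apart. Single scores overlapped: late GC replicate 3 had 2.024 for neutrophils (peak GC replicate 3: 2.108), and early GC replicate 2 had 3.315 for macrophages, above 2 late libraries (2.704 and 2.616). The labels name sorting, but not its purity.

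Ddx3y, Eif2s3y and Kdm5d were at the floor in 12 libraries and present in the other 12. A lowest Xist of 6.28 in the latter argues against males alone there. Animals of both sexes in the naive and in vitro groups and females in the others may explain the split: the lowest Xist without Y-linked genes lay 0.42 above the highest with them. The shares of X-linked (83.5% of 382) and autosomal genes (79.6% of 11449) that changed between peak GC and naive differed by 3.9 points, but are too near saturation to weigh sex as a cause. Sex and group remain confounded.

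Camera called immediate-early genes lower than in naive cells in all 5 groups compared with them, but adjusted p = 0.257, 0.403, 0.483, 0.216 and 0.239 with an estimated correlation for peak GC, in vivo activated, 4 h, 12 h and 24 h cells. Handling alike in all cells from animals was not tested, since the medians of -1.3 in in vivo activated and -2.16 in peak GC cells restate the pattern. Handling that differed between groups stays open: camera called heat shock genes lower in 0 of 5 comparisons, with the highest median 1.54, which decides nothing. A difference between the cell groups was not tested apart from handling.

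For each of the 13 comparisons, the 10 splits of its 6 libraries are too few for a share under 0.05, and the real one gave the most genes by limma. Real counts were 9034, 9551, 9521, 9995 and 10174 for peak GC, in vivo activated, 4 h, 12 h and 24 h against naive, 7612 and 9154 for peak GC against in vivo activated and 24 h, 8612 for in vivo activated against 24 h, those above for GC stages, and 8470 and 7915 for 12 h against 4 h and 24 h against 12 h. Other splits gave at most 0, but mixing the groups widens their spread, so the counts decide nothing.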
